A study of Saccharomyces cerevisiae with 10 samples.

How the data were processed

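The samples were commercial baker's yeast (Saccharomyces cerevisiae), grown in fed-batch culture. Per the labels' protocols, compressed cells lay on aluminium trays in a dry oven, where they were dried with blown air at 37 degrees. Cells were taken at 0, 1, 2, 4 and 8 h of drying. Per the series' design text, RNA was extracted with hot phenol, poly(A) RNA was enriched with an oligo(dT) kit, and biotin-labelled cRNA was hybridised to Affymetrix Yeast Genome S98 arrays, with duplicate experiments done independently. This gives 10 arrays in 5 groups of 2. No release of the genome is named in the sources used here, so genes are given by symbol and no coordinates are printed.

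The deposited values were linear signal intensities, 1 column per array, with no value below 0. The submitters' processing notes name GCOS, Affymetrix's array software, and its version was not given in the sources used here. Per the labels, the authors also made a table of ratios, with a floor of 0.01, division of each array by its 50th percentile, and division of the dried samples by the 0 h median. Those steps had not been applied to the intensities used here, because the array medians ranged from 23.6 to 115.4. No detection calls were used here, so a dim value cannot be told from background. Arrays have no read depth, and their number limits the precision.

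Of 9335 probe sets on the array, 60 were controls and were left out of scaling and testing. Among the 9275 others, 6504 were assigned to 1 gene, 328 to several genes and 2443 to none in the platform annotation used here. A total of 6832 probe set identifiers matched that annotation. Symbols were updated through gene identifiers to the R64 reference table, which was used for names and gene types only. Each array was divided by its median over the non-control probe sets, floored at 0.1 of that median and converted to log2. Probe sets with a mean log2 value under -2.32 (0.2 of the median) were left out. Probe sets with several genes or none were left out of the gene-level tests, and each gene was represented by its brightest probe set. This left 5365 of 5656 genes. Several probe sets were tested for 269 genes, and 0 of these genes had probe sets called in opposite directions. On this array, many probe sets for tRNA genes, ribosomal protein pairs and other gene families also bind near-identical copies, so their values may mix family members.

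Changes were tested with limma 3.58.1 in R 4.3.3. A model of group means was fitted to all 10 arrays, so that the groups shared 1 estimate of the spread, followed by eBayes with an intensity trend. Adjusted p values are two-sided and adjusted by the Benjamini-Hochberg method over 5365 genes, with a threshold of 0.05. The 8 comparisons were each dried time against 0 h, each step from 1 time to the next, and 8 h against 1 h. An F test over the 4 comparisons with 0 h asked whether a gene changed at any time. Errors of log2 changes are limma's standard errors (SE) with n = 2 arrays per time. Each SE draws on all 10 arrays, so it need not reflect how far apart the 2 arrays of 1 time lie. A change against a group whose arrays were all at the floor is printed as a lower bound, computed against the floor.

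There were 36 gene lists, fixed before the data were examined along with the design, the tests, most of the other settings tried and the rule for named genes. They covered heat shock chaperones, general stress response genes, trehalose metabolism, glycogen metabolism, glycerol and osmotic stress response, hydrophilins, oxidative stress defence, the proteasome, autophagy, vacuolar proteases, cytosolic and mitochondrial ribosomal proteins, ribosome biogenesis, RNA polymerase I and III subunits, translation factors, glycolysis and fermentation, gluconeogenesis and the glyoxylate cycle, the tricarboxylic acid cycle, and the respiratory chain with ATP synthase. They also covered fatty acid beta-oxidation and peroxisomes, fatty acid synthesis, ergosterol synthesis, amino acid biosynthesis, sulfur amino acid synthesis, nitrogen catabolite repressed genes, phosphate starvation genes, the iron regulon, the cell wall, endoplasmic reticulum chaperones with the unfolded protein response, histones, cell cycle and DNA replication, DNA damage response, hexose transport and sugar utilisation, and multidrug resistance. Mating and haploid-specific genes and sporulation genes stood for other kinds of yeast cell. Each list was tested against all other genes with camera at a preset correlation of 0.01, with p values adjusted over all lists and comparisons. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way, were run as alternatives.

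Named genes were chosen as follows. For each comparison with 0 h, they were the 6 largest rises and 6 largest falls among genes past the threshold that changed at least 2-fold, with both arrays of that time above or below both 0 h arrays. Added to these were the 2 members with the smallest adjusted p that moved with each list that passed, with a limit of 30 genes. For each step, the 3 largest rises and 3 largest falls were named. The genes HSP104, HSP26, HSP12, SSA4, TPS1, TSL1, NTH1, GPD1, CTT1, SIP18, MSN2, MSN4, HSF1 and ACT1 were reported whatever their result. Other genes are identified in the text as chosen after their values were seen.

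The same steps were tested on simulated data with 5365 genes and the spread of these arrays, over 20 runs with 200 genes changed at 1 h against 0 h. They recovered 32.1% of genes changed by 1 log2 unit, 74.9% at 1.5, 88.2% at 2 and 96% at 3 in that comparison. On average 7% of the genes called in these runs were unchanged ones. The simulated noise was normal, independent between genes and equal on all arrays. In the data, the root mean square deviation from the group mean was 0.215 at 1 h and 0.375 at 8 h. These percentages therefore hold for the simulated setting and may not hold for the data. The alternatives covered 4 other scalings, 3 other floors, 2 other filters, 3 other variance models, a fit with the compared groups alone, the replicate number as a block, all probe sets, the mean over a gene's probe sets, a stricter threshold and each array left out in turn. Of the scalings, no scaling and the 75th percentile move all genes of an array alike, apart from the floor and the filter on dim probe sets. A list's distance from all genes therefore hardly changes with them, and they are no check of that distance. Leaving out the dimmest array at 2 h and at 8 h, and testing protein-coding genes alone, were chosen after seeing the data.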

Results

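The series asked how gene expression in commercial baker's yeast changes while the compressed cells are dried in warm air. Genome-wide expression was measured at 0 h and after 1, 2, 4 and 8 h of drying, with 2 arrays at each time. Every dried group had been in the warm air of the oven, and no group was kept warm, or kept as long, without drying. Changes against 0 h can therefore come from heat, time in the oven or water loss, and these cannot be told apart here. Array medians of the signal intensity ranged from 23.6 on replicate 1 at 8 h to 115.4 on replicate 2 at 8 h. The next dimmest array was replicate 1 at 2 h, with a median of 28.7. The ratio of 3' to 5' actin signal, a measure of RNA integrity and of cDNA length, was 6.44 and 6.64 on these arrays, 5.38 on replicate 1 at 0 h, and 2.62 to 3.9 on the other 7 arrays. Across all genes tested, replicate arrays had Pearson correlations of 0.973 at 0 h, 0.98 at 1 h, 0.942 at 2 h, 0.962 at 4 h and 0.942 at 8 h. The share of probe sets with identical values on any pair of arrays was at most 0.61%.

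After 1 h of drying, 119 genes had risen and 21 had fallen against 0 h. The largest rise was that of SSA4, a stress-inducible Hsp70 chaperone, at 4.15 ± 0.31 log2 units (SE, n = 2 arrays per time, adjusted p = 3.57e-06), which is 17.8-fold. Next came HXT1, a low-affinity glucose transporter (3.45 ± 0.38), YKL107W (3.32 ± 0.29), SSA3, another inducible Hsp70 (3.07 ± 0.22), GNP1, a glutamine permease (2.67 ± 0.33), and HSP82, an Hsp90 chaperone (2.61 ± 0.33). The largest falls were DDL1, a phospholipase, at -2.15 ± 0.50 (adjusted p = 0.034), YNR014W at -1.71 ± 0.31, and the tRNA genes YNCB0015W, YNCJ0011W, YNCJ0008W and YNCJ0014C, at -1.47 to -1.42. All 119 genes that rose were protein-coding, and 9 of the 21 that fell were tRNA genes. At an unadjusted p under 0.05 there were 744 genes, 553 higher and 191 lower, where 268 would be expected by chance.

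Chaperones formed the list with the largest shift at 1 h. Warm air, time in the oven and water loss came together in this comparison, so the shift cannot be assigned to any of them. Of 30 heat shock chaperone genes measured, 14 rose, 0 fell and 16 did not pass, and 23 rose when adjusted over the list alone. The list's median change was 1.20 log2 units (camera adjusted p = 1.22e-24), with adjusted p = 0.94 with an estimated correlation. Besides SSA3, SSA4 and HSP82, HSP104, which dissolves protein aggregates, rose by 2.17 ± 0.30 (adjusted p = 0.0014). Hsp70 genes resemble each other in sequence, so their probe sets may share signal. In the list of fatty acid beta-oxidation and peroxisomes, 7 of 33 genes rose and 0 fell, or 16 when adjusted over the list alone, with a median of 0.75 (camera adjusted p = 3.08e-11). Its leading members were PXA2, part of the peroxisomal fatty acid transporter (2.31 ± 0.25), and FAA2, a fatty acyl-CoA synthetase (1.97 ± 0.26). The proteasome list had a median of 0.47, with 3 of 34 genes raised over all genes and 3 when adjusted over the list alone. These included RPN4, the activator of proteasome genes (1.40 ± 0.25), and RPN5, a lid subunit (1.22 ± 0.25). Adjusted p values with an estimated correlation were 0.94 for the peroxisomal and the proteasome list.

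Smaller upward shifts at 1 h were those of autophagy, gluconeogenesis and general stress response genes. The autophagy list had a median of 0.41, with 3 of 31 genes raised, or 4 when adjusted over the list alone. ATG1, the kinase that starts autophagy, rose by 1.53 ± 0.29, and ATG7 by 1.16 ± 0.24. In gluconeogenesis and the glyoxylate cycle, 2 of 21 genes rose, or 5 when adjusted over the list alone, with a median of 0.43. They were SIP4, a transcriptional activator of this pathway (2.13 ± 0.35), and ICL1, isocitrate lyase (1.39 ± 0.34). Of 30 general stress response genes, 6 rose, or 7 when adjusted over the list alone, with a median of 0.29. This list shared 10 of its measured genes with other lists, SSA4 among them, and RTN2, a reticulon, rose by 2.19 ± 0.39. Each of these 3 lists passed camera, with an adjusted p of 0.0019 for autophagy and for gluconeogenesis and 0.0011 for general stress, and each had adjusted p = 0.94 with an estimated correlation. The autophagy median was 0.27 with the 75th percentile. The gluconeogenesis median was 0.70 and 0.17 without replicates 1 and 2 of 0 h and 0.29 with the 75th percentile. The general stress median was 0.50 and 0.17 without replicates 1 and 2 of 0 h, 0.44 without replicate 2 of 1 h and 0.15 with the 75th percentile.

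Lists with a downward shift at 1 h moved little. Amino acid biosynthesis had a median of -0.30, with 0 of 57 genes raised and 1, asparagine synthetase ASN1, lowered (-1.09 ± 0.24, adjusted p = 0.026). The median was -0.29 for 30 sulfur amino acid genes, -0.20 for 108 ribosome biogenesis genes and -0.19 for 82 cytosolic ribosomal protein genes, and 0 genes of these 3 lists passed over all genes or when adjusted over the list alone. Cell wall genes had a median of -0.23, with 1 of 40 lowered on both counts. Examples that did not pass were LYS12 (-0.75 ± 0.25), MUP3, a methionine permease (-0.69 ± 0.25), SUL2, a sulfate permease (-0.52 ± 0.23), NSR1 (-0.84 ± 0.26), YTM1 (-0.62 ± 0.23), RPL15A (-0.50 ± 0.23) and RPL36B (-0.73 ± 0.37). For RPL36B the SD over the 1 h arrays was 1.095, so its direction is uncertain. The 5 lists passed camera at adjusted p values from 1.85e-05 for amino acid biosynthesis to 0.030 for the cell wall, and all had adjusted p = 0.94 with an estimated correlation. The cell wall call was lost without replicate 1 of 0 h or of 1 h or without scaling, and the ribosome biogenesis call, like that of gluconeogenesis, without replicate 2 of 0 h. The amino acid median was -0.18 without replicate 2 of 1 h. The ribosome biogenesis median was -0.34 with the 75th percentile. The cytosolic ribosomal protein median was -0.06 without replicate 1 of 0 h, -0.12 without replicate 2 of 1 h and -0.33 with the 75th percentile. The cell wall median was -0.12 without replicate 1 of 0 h and -0.37 with the 75th percentile.

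Among stress genes that did not pass at any time, several had a probe set signal far above the array median at 0 h, though probe sets differ in affinity and do not rank transcripts by abundance. HSP12, a membrane-protecting small heat shock protein, stood at 7.30 log2 units above the array median at 0 h and changed by 0.10 ± 0.49 at 1 h and 0.01 ± 0.49 at 8 h. At 8 h it stood at 8.12 on the dim replicate 1 and at 6.51 on replicate 2. The 99th percentile of the signal over the array median was 138.3 and 68.5 on these arrays. The scaled values of bright probe sets thus differed between arrays, so small mean changes of such genes do not show that they were stable. HSP26 stood at 5.43 and changed by 0.54 ± 0.31 at 1 h, and SIP18, a hydrophilin, stood at 6.32 and changed by less than 0.01 ± 0.46. The trehalose genes TPS1, TSL1 and NTH1 changed by -0.09 ± 0.29, 0.31 ± 0.29 and 0.60 ± 0.28 at 1 h, GPD1, which makes glycerol, by 0.28 ± 0.28, and the catalase CTT1 by -0.07 ± 0.29. The stress regulators MSN2, MSN4 and HSF1 changed by 0.48 ± 0.30, -0.64 ± 0.27 and -0.44 ± 0.37, and actin, ACT1, by -0.17 ± 0.38. The SD over the 1 h arrays was 0.463 for MSN4 and 0.851 for HSF1, so the direction of HSF1 is uncertain.

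The count of 140 genes at 1 h rested on every array of the comparison. It was 47 without replicate 1 and 29 without replicate 2 of 0 h, and 18 without replicate 1 and 42 without replicate 2 of 1 h, and among 23 named calls the 8 that held in each case were SSA4, HXT1, YKL107W, SSA3, GNP1, HSP82, PXA2 and FAA2. The count was 1 without scaling, 36 without a variance trend, 42 with a higher floor, 344 without the dimmest arrays of 2 h and 8 h, 501 with array weights and 530 with only the compared groups in the fit. Scaling by the 75th percentile moved the median of all genes at 1 h from 0.04 to -0.11.

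**Figure D1:**
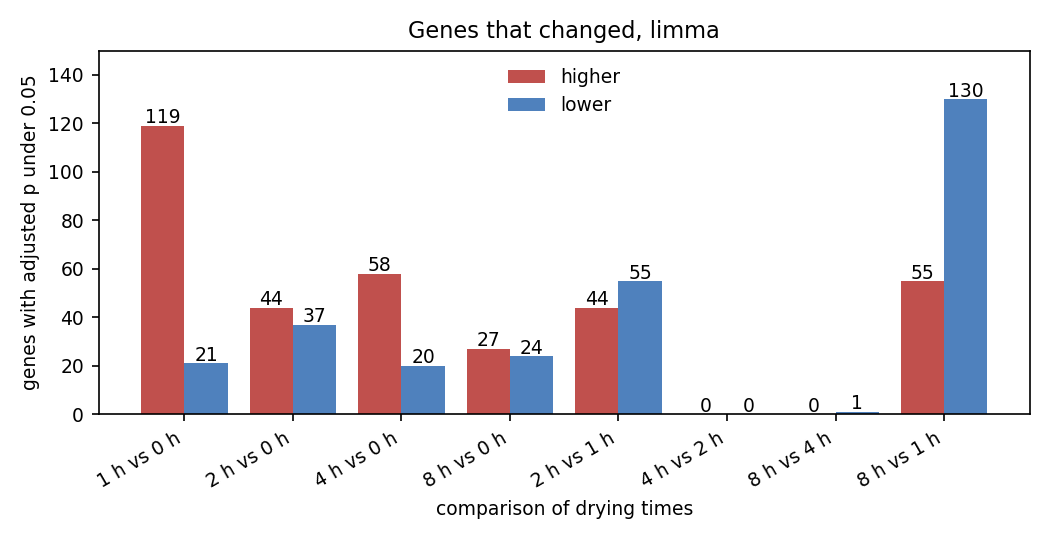
Number of genes with a limma adjusted p under 0.05 (vertical axis) in each comparison of drying times (horizontal axis), higher in red and lower in blue. The rise to 119 higher genes at 1 h and the 130 genes lower at 8 h than at 1 h are the tallest bars.

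After 2 h, 44 genes were higher and 37 lower than at 0 h. YKL107W had the largest rise (3.67 ± 0.29, adjusted p = 2.17e-05), followed by ALD3, an aldehyde dehydrogenase (2.98 ± 0.41), SSA4 (2.93 ± 0.31) and CIN5, a transcription factor (2.63 ± 0.24). TPO3, a polyamine exporter, and BUD2, which acts in bud site selection, were at the floor on both 0 h arrays and rose at least 11.4-fold and at least 6.1-fold (adjusted p = 0.042 and 0.017). The bound for TPO3 was 20.5-fold and 6.3-fold without replicates 1 and 2 of 2 h. The largest falls were SNR78, a small nucleolar RNA (-2.68 ± 0.35), VID24, part of a ubiquitin ligase for gluconeogenic enzymes (-2.55 ± 0.33), YKR075C (-2.39 ± 0.39), HXT4, a high-affinity glucose transporter (-2.34 ± 0.32), DIP5, a permease for glutamate and aspartate (-2.10 ± 0.33), and YRO2 (-2.05 ± 0.30). Of the fixed genes, HSP104 was higher by 2.10 ± 0.30 (adjusted p = 0.0023). The others, apart from SSA4, did not pass, GPD1 at 0.76 ± 0.28 and MSN4 at -0.68 ± 0.27 being the farthest from 0.

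Chaperone and peroxisomal genes stayed up at 2 h as lists. Of 30 chaperone genes, 4 were higher, or 7 when adjusted over the list alone, with a median of 0.62 (camera adjusted p = 1.74e-06), SSA3 among them at 1.99 ± 0.22. Of 33 peroxisomal genes, 5 were higher, or 11 when adjusted over the list alone, with a median of 0.49 (camera adjusted p = 9.04e-10), PXA2 at 2.17 ± 0.25 and FAA2 at 1.499 ± 0.26. General stress genes had a median of 0.27, with 6 of 30 higher and 2 lower, or 7 and 2 when adjusted over the list alone. Hexose transport and sugar utilisation had a median of -0.49, with 0 of 23 genes higher and 3 lower, or 1 and 5 when adjusted over the list alone, including HXT4 and MTH1, a repressor of hexose transporter genes (-1.13 ± 0.24). Sulfur amino acid genes had a median of -0.50, with 1 of 30 lower on both counts, MUP3 at -1.09 ± 0.25, and SUL1 did not pass at -0.71 ± 0.24. Each of these 5 lists passed camera and had adjusted p = 0.94 with an estimated correlation. Leaving out the scaling moved the median of all genes at 2 h to -0.67. The chaperone, peroxisomal and general stress medians were then -0.01, -0.14 and -0.36. All genes of an array move alike in this setting, so each list stayed above all genes. Each still passed camera. The chaperone median was 0.32 without replicate 2 of 0 h, 0.27 without replicate 1 of 2 h and 0.37 after quantile normalization. The peroxisomal median was 0.76 and 0.32 without replicates 1 and 2 of 0 h. The general stress median was 0.47 and 0.095 without replicates 1 and 2 of 0 h, 0.01 and 0.515 without replicates 1 and 2 of 2 h, 0.05 after quantile normalization and 0.15 after cyclic loess.

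A further 5 lists passed camera at 2 h with 0 members past the threshold, over all genes or adjusted over the list alone. The median was 0.75 for 24 mating and haploid-specific genes, -0.26 for 57 amino acid biosynthesis genes, -0.38 for 33 translation factors, -0.23 for 26 ergosterol genes and -0.26 for 74 mitochondrial ribosomal protein genes. Camera adjusted p values ran from 0.020 to 0.044, all with adjusted p = 0.94 with an estimated correlation. The mating genes were dim, and 10 of the 24 were at the floor on some array, among them STE6 (1.39 ± 0.64) and STE18 (1.51 ± 0.71) on 1 of the 0 h arrays. Members of the other lists that did not pass included ASN1 (-0.85 ± 0.24), HOM3 (-0.83 ± 0.26), PRT1 (-0.99 ± 0.28), SUP35 (-1.18 ± 0.38), IDI1 (-1.09 ± 0.29), ERG1 (-0.73 ± 0.26), MRPS9 (-0.94 ± 0.32) and MRP2 (-0.83 ± 0.29). For SUP35 the SD over the 2 h arrays was 0.761. Without the dim replicate 1 of 2 h, the calls of mating, general stress, amino acid, translation factor and ergosterol genes were lost. Those of mating, amino acid, translation factor and mitochondrial ribosomal genes were lost without replicate 2 of 0 h, the mitochondrial one also without replicate 2 of 2 h, and ergosterol without replicate 1 of 0 h. Ergosterol and mitochondrial ribosomal calls were also lost after quantile normalization and after cyclic loess, the mating call after quantile normalization, and the amino acid, translation factor, ergosterol and mitochondrial ribosomal calls without scaling. The mating median was 0.39 without replicate 2 of 0 h. The amino acid median was -0.14 and -0.46 without replicates 1 and 2 of 2 h and -0.16 with the 75th percentile. The translation factor median was -0.21 without replicate 1 of 2 h. The ergosterol median was -0.04 and -0.38 without replicates 1 and 2 of 2 h and -0.13 with the 75th percentile. The mitochondrial ribosomal protein median was -0.17 without replicate 2 of 0 h, -0.15 after cyclic loess and -0.16 with the 75th percentile. With the 75th percentile the median of all genes at 2 h also moved, from -0.05 to 0.05.

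The count of 81 genes at 2 h was 17 without replicate 1 and 39 without replicate 2 of 0 h, 193 without replicate 1 and 185 without replicate 2 of 8 h, and 252 without the dimmest arrays of 2 h and 8 h. It was 0 without scaling, 17 with a higher floor and 163 after quantile normalization, where 105 genes were higher and 58 lower. With the replicate number as a block it was 124, with 80 genes higher and 44 lower. Without the dim replicate 1 of 2 h the split turned round, with 21 genes higher and 69 lower, and without the dimmest arrays of 2 h and 8 h it was 96 and 156. Of 18 named calls at 2 h, 11 held with each array left out, those of ALD3, CIN5, HSP104, HXT4, PXA2, SNR78, SSA3, SSA4, VID24, YKL107W and YRO2.

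After 4 h, 58 genes were higher and 20 lower. SSA4 led again (3.62 ± 0.31, adjusted p = 4.41e-05), with HXT1 at 3.01 ± 0.38 and YKL107W at 2.72 ± 0.29. The tRNA genes SUF5 (3.10 ± 0.42), SUF3 (2.74 ± 0.27) and CDC65 (2.56 ± 0.42) also rose, and 13 of the 58 genes that rose were tRNA genes. The largest falls were RMD6 (-2.53 ± 0.59, adjusted p = 0.049), DIP5 (-2.31 ± 0.33), the tRNA genes YNCM0004C (-2.05 ± 0.29), YNCD0011W (-2.04 ± 0.27) and YNCJ0011W (-1.99 ± 0.26), and the small nucleolar RNA SNR34 (-2.03 ± 0.36). RMD6 had 3 probe sets, which gave -2.53, -1.73 and -0.40 at 4 h. HSP104 was higher by 1.88 ± 0.30 (adjusted p = 0.0050). The fixed genes other than HSP104 and SSA4 did not pass, NTH1 being the farthest from 0 at 0.86 ± 0.28.

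Of 30 chaperone genes, 7 were higher at 4 h, or 13 when adjusted over the list alone, with a median of 0.49 (camera adjusted p = 8.13e-09), BTN2, which sequesters misfolded proteins, at 2.26 ± 0.32. Peroxisomal genes had a median of 0.55 (camera adjusted p = 3.69e-08), with 4 of 33 higher, or 10 when adjusted over the list alone. They included both parts of the fatty acid transporter, PXA1 (1.75 ± 0.29) and PXA2 (1.66 ± 0.25). General stress genes had a median of 0.17, with 6 of 30 higher, or 6 higher and 1 lower when adjusted over the list alone, ALD3 at 2.32 ± 0.41. Hexose transport genes had a median of -0.35, with HXT1 the 1 higher gene of 23 and the glucose repressor MIG2 (-1.74 ± 0.35) and HXT8 (-1.27 ± 0.27) the 2 lower ones, or 1 and 4 when adjusted over the list alone. Each of these 4 lists had adjusted p = 0.94 with an estimated correlation. The chaperone median was 0.76 without replicate 1 of 0 h. The general stress median was 0.30 and 0.07 without replicates 1 and 2 of 0 h and 0.06 and 0.31 without replicates 1 and 2 of 4 h. The hexose transport median was -0.21 and -0.58 without replicates 1 and 2 of 0 h.

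The other lists that passed camera at 4 h all had negative medians. Sulfur amino acid genes had a median of -0.23, with 1 of 30 lower, MUP3 at -1.56 ± 0.25, or 2 when adjusted over the list alone, while SAM2, at -1.27 ± 0.32, did not pass over all genes. For SAM2 the SD over the 4 h arrays was 0.753. The median was -0.14 for 57 amino acid genes, -0.25 for 20 glycolysis and fermentation genes and -0.17 for 74 mitochondrial ribosomal protein genes, with 0 members past the threshold over all genes or adjusted over the list alone. Members that did not pass were ARG1 (-1.63 ± 0.51), HIS4 (-0.80 ± 0.26), PDC6 (-0.71 ± 0.25), HXK2 (-1.25 ± 0.44), MRPL44 (-0.83 ± 0.29) and MRPS8 (-0.92 ± 0.34). The SD over the 4 h arrays was 1.655 for ARG1 and 1.37 for HXK2, so the size of their changes is uncertain. These 4 lists had adjusted p = 0.94 with an estimated correlation, and without scaling their medians were 0.03, 0.12, 0 and 0.08, all below the median of all genes, 0.27. The sulfur amino acid and amino acid calls held without scaling, and the other 2 were lost. The calls of amino acid and glycolysis genes were lost without replicate 2 of 4 h, that of glycolysis also without replicate 1 of 0 h, that of mitochondrial ribosomal proteins without replicate 2 of 0 h or replicate 1 of 4 h, and that of general stress genes without replicate 2 of 0 h. The sulfur amino acid median was -0.38 and -0.13 without replicates 1 and 2 of 4 h. The amino acid median was -0.08 and -0.22 without replicates 1 and 2 of 0 h and -0.28 and -0.003 without replicates 1 and 2 of 4 h. The glycolysis median was -0.01 and -0.48 without replicates 1 and 2 of 0 h and -0.38 and -0.07 without replicates 1 and 2 of 4 h. The mitochondrial ribosomal protein median was -0.11 without replicate 2 of 0 h and -0.105 without replicate 2 of 4 h.

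The count of 78 genes at 4 h was 26 without replicate 1 and 31 without replicate 2 of 0 h, 30 without replicate 2 of 4 h, 130 without either 8 h array and 232 without the dimmest arrays of 2 h and 8 h. It was 0 without scaling, 6 with a higher floor and 50 over protein-coding genes alone. The split was 28 higher and 33 lower without replicate 1 of 4 h and 13 and 17 without replicate 2. Of 20 named calls at 4 h, 11 held with each array left out, those of BTN2, DIP5, HXT1, PXA2, SSA4, SUF3, SUF5, YKL107W, YNCD0011W, YNCJ0011W and YNCM0004C, and that of HSP104 was lost without replicate 2 of 0 h or of 4 h.

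After 8 h, 27 genes were higher and 24 lower than at 0 h, of which 14 and 14 were protein-coding. The largest rises were those of the tRNA gene SUF5 (3.01 ± 0.42), SSA4 (2.90 ± 0.31, adjusted p = 2.47e-04), and the tRNA genes SUF3 (2.70 ± 0.27), HSX1 (2.30 ± 0.37) and CDC65 (2.28 ± 0.42, or 1.435 without replicate 1 of 8 h). The SD over the 8 h arrays was 1.106 for SUF5, 0.985 for HSX1 and 1.192 for CDC65, so the size of their rises is uncertain. BUD2 rose at least 5.2-fold from the floor (adjusted p = 0.045). DIP5 had the largest fall, -3.35 ± 0.33 (adjusted p = 1.89e-04), or 10.2-fold. SGF29, a subunit of the SAGA coactivator, was at the floor on both 8 h arrays and was at least 5.5-fold lower (adjusted p = 0.049). The tRNA genes YNCB0015W, YNCE0010W, YNCM0004C and YNCK0006C fell, with log2 changes of -2.24, -2.18, -2.13 and -2.10. HSP104 was higher by 1.46 ± 0.30 (adjusted p = 0.037), and the fixed genes other than HSP104 and SSA4 did not pass, GPD1 being the farthest from 0 at 0.63 ± 0.28.

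Chaperone genes kept 4 of 30 members higher at 8 h, or 6 higher and 1 lower when adjusted over the list alone, with a median of 0.19 (camera adjusted p = 0.018) and BTN2 at 1.66 ± 0.32. This median was 0.39 and -0.085 without replicates 1 and 2 of 0 h, 0.305 and 0.36 without replicates 1 and 2 of 8 h, 0.06 after quantile normalization and 0.065 after cyclic loess. Without scaling it was -0.12, above the -0.29 of all genes, and the call held. The call was lost without replicate 2 of 0 h or of 8 h. The peroxisomal list had a median of 0.39 with 0 of 33 genes past the threshold on either count, PXA1 at 0.96 ± 0.29 and PXA2 at 0.79 ± 0.25 (camera adjusted p = 2.32e-04). Hexose transport genes had a median of -0.13, with HXT1 the 1 higher gene of 23 and HXT4 (-1.82 ± 0.32) and HXT8 (-1.26 ± 0.27) the 2 lower ones, or 1 and 5 when adjusted over the list alone. The median was -0.17 for 108 ribosome biogenesis genes and -0.16 for 74 mitochondrial ribosomal protein genes, with 0 members past the threshold on either count. Members that did not pass were CBF5 (-1.06 ± 0.26), NOP56 (-0.96 ± 0.29), MRPS8 (-1.02 ± 0.34) and MRPL31 (-0.84 ± 0.29). All 5 lists had adjusted p = 0.94 with an estimated correlation. The calls of the ribosome biogenesis and mitochondrial ribosomal lists were lost without the dim replicate 1 of 8 h or replicate 2 of 0 h, the latter also without replicate 1 of 2 h, and the hexose call without replicate 1 of 0 h or 2 h or replicate 2 of 4 h or 8 h. Both ribosomal lists lost their call without scaling, and the mitochondrial one also after quantile normalization. The hexose transport median was -0.05 and -0.33 without replicates 1 and 2 of 0 h, -0.40 and -0.23 without replicates 1 and 2 of 8 h and -0.27 after quantile normalization. The ribosome biogenesis median was -0.01 and -0.28 without replicates 1 and 2 of 8 h. The mitochondrial ribosomal protein median was -0.02 and -0.25 without replicates 1 and 2 of 8 h.

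The count of 51 genes at 8 h was 14 without replicate 1 and 25 without replicate 2 of 0 h, 28 without replicate 1 and 186 without replicate 2 of 8 h. It was 0 without scaling, 6 with a higher floor, 17 over protein-coding genes alone and 97 after quantile normalization. With the replicate number as a block it was 96, with 58 genes higher and 38 lower. The split was 8 higher and 20 lower without the dim replicate 1 of 8 h and 30 and 51 without the dimmest arrays of 2 h and 8 h. Of 16 named calls at 8 h, 8 held with each array left out, those of DIP5, SSA4, SUF3, SUF5, YNCB0015W, YNCE0010W, YNCK0006C and YNCM0004C. The calls nearest the threshold were lost in 12 of 29 settings for HSP104, among them without either 0 h array, either 4 h array or replicate 1 of 8 h, in 18 of 29 for HXT8, in 16 of 28 for BUD2 and in 19 of 28 for SGF29.

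**Figure D2:**
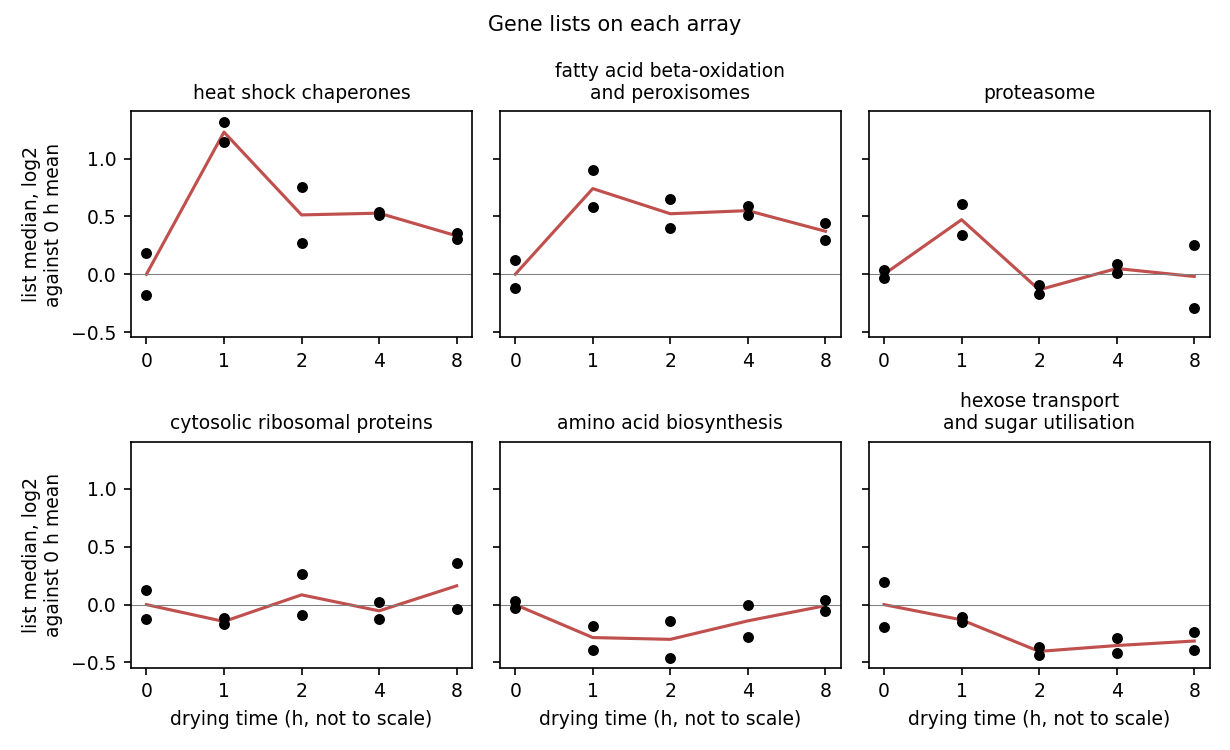
Median log2 signal of the genes of 6 lists against their 0 h mean (vertical axis) at each drying time in hours (horizontal axis, not to scale), with a point for each array and a line through the means of the 2 arrays. Chaperone genes reached 1.14 and 1.32 on the 1 h arrays and 0.31 and 0.36 on the 8 h arrays.

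Taking all times together, the F test called 176 genes. It called 85 and 84 without replicates 1 and 2 of 0 h, 59 and 65 without replicates 1 and 2 of 1 h, 266 without replicate 1 of 2 h and 374 without replicate 2 of 8 h. Across the 4 comparisons with 0 h, 148 genes were higher and 54 lower at 1 or more times, and 0 genes were called in opposite directions. Genes higher at all 4 times numbered 10 and genes lower at all 4 times also 10. The higher ones included the chaperone genes SSA3, SSA4, HSP104 and BTN2, with ALD3 and YKL107W. Also among them were STL1, a glycerol transporter (2.56, 1.74, 2.21 and 2.16 at 1, 2, 4 and 8 h), ARO9, an aromatic aminotransferase (2.57, 2.58, 2.14 and 1.96), PEX9, a peroxisomal import receptor (1.63, 2.22, 2.19 and 1.61), and SWR1, a chromatin remodeller (1.44, 1.67, 1.44 and 1.30), and the lower ones were HXT8, the transcription factor SOK2 (-1.15, -1.64, -1.56 and -1.31) and 8 tRNA genes. STL1, ARO9, PEX9, SWR1 and SOK2 were chosen after their values were seen.

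Calls shared between times are counted on the same 0 h arrays. The 1 h and 2 h comparisons shared 33 higher and 12 lower genes, where independent lists of these sizes would share 0.98 and 0.14 and simulated unchanged groups 0.02 in all. The 1 h and 8 h comparisons shared 12 higher and 10 lower genes, against 0.6 and 0.09 for independent lists, and the 4 h and 8 h comparisons 23 and 15, against 0.29 and 0.09. The correlation of log2 changes across genes, which are not independent replicates, was 0.33 between 1 h and 8 h and 0.63 between 2 h and 4 h, beside 0.5 in the simulations. The covariance was 0.095 and 0.192, beside 0.082 in the simulations. The 0 h arrays were not divided between comparisons, which would leave 1 array on each side, so part of the excess may come from the shared arrays. The figure for independent lists ignores those arrays, and the simulated groups share few calls because no gene changes in them. Neither figure can therefore show how many of the shared calls come from the shared arrays.

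From 1 h to 2 h, 44 genes rose and 55 fell. Of the 44 that rose, 41 were tRNA genes, led by SUF2 (3.23 ± 0.75) and SUF5 (2.83 ± 0.42), and TPO3, at the floor on both 1 h arrays, was higher at 2 h by at least 11.4-fold (adjusted p = 0.040), or 20.5-fold and 6.3-fold without replicates 1 and 2 of 2 h. Of the 55 that fell, 54 were protein-coding. GPB2, a regulator of protein kinase A, fell by 2.54 on the log2 scale (adjusted p = 0.049) with 1 of the 2 h arrays at the floor and by 1.33 without replicate 2 of 2 h, AGP1, an amino acid permease, changed by -2.18 ± 0.29 and HXT1 by -2.05 ± 0.38. Chaperone genes had a median of -0.85, with 0 of 30 higher and 7 lower, or 17 lower when adjusted over the list alone (camera adjusted p = 3.23e-11). The proteasome list had a median of -0.63, with 1 of 34 genes lower, or 12 when adjusted over the list alone (camera adjusted p = 3.07e-08). Cytosolic ribosomal protein genes had a median of 0.23 with 0 of 82 past the threshold on either count (camera adjusted p = 1.68e-05), a call that was lost without the dim replicate 1 of 2 h or without scaling, where their median was -0.41 and that of all genes -0.755. These 3 lists had adjusted p = 0.94 with an estimated correlation. The proteasome median was -0.42 after cyclic loess and -0.39 with the 75th percentile. The cytosolic ribosomal protein median was 0.08 and 0.50 without replicates 1 and 2 of 2 h and 0.47 with the 75th percentile.

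Without the dim replicate 1 of 2 h, 24 genes were higher and 119 lower from 1 h to 2 h, and without the dimmest arrays of 2 h and 8 h 89 and 311. The count of 99 genes was 0 without either 1 h array, 11 without replicate 2 of 2 h, 33 and 34 without replicates 1 and 2 of 0 h, 58 and 40 without replicates 1 and 2 of 4 h, and 210 and 215 without replicates 1 and 2 of 8 h. Scaling by the 75th percentile moved the median of all genes from -0.12 to 0.13 and gave 36 higher and 13 lower genes, and quantile normalization gave 65 and 48. Of the 6 named calls in this step, 0 held with each array left out.

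In the later steps few genes were called, which with 2 arrays per time does not show that few genes changed. At an unadjusted p under 0.05 in limma, 268 genes would be expected by chance in each step. The genes below it were 300 higher and 99 lower from 2 h to 4 h, and 137 and 263 from 4 h to 8 h. The median of all genes was 0.077 and -0.024 in these steps, so an offset left by the scaling was not separated from changes of single genes. From 2 h to 4 h, limma called 0 genes, with 399 at an unadjusted p under 0.05, but 29 without replicate 1 of 2 h, 16 without replicate 1 of 4 h and 84 without the dimmest arrays of 2 h and 8 h. From 4 h to 8 h it called 1 gene, CIN5, which fell by 1.67 on the log2 scale (SE 0.24, adjusted p = 0.030), with 400 genes at an unadjusted p under 0.05. The count was 0 without either 0 h array or either 1 h array, and 21, 5 and 38 genes without replicate 1 of 4 h and replicates 1 and 2 of 8 h. The proteasome list shifted by 0.32 from 2 h to 4 h and by -0.29 from 4 h to 8 h, and cytosolic ribosomal protein genes by -0.15 and 0.21. Chaperone genes shifted by -0.37 from 4 h to 8 h, peroxisomal genes by -0.16 and amino acid biosynthesis genes by 0.23. In these 7 shifts 0 members passed over all genes, while 1 chaperone gene was lower and 3 amino acid genes were higher from 4 h to 8 h when adjusted over the list alone. All 7 had adjusted p = 0.94 with an estimated correlation. From 2 h to 4 h, the ribosomal protein call was lost without the dim replicate 1 of 2 h or replicate 2 of 4 h, and that of the proteasome was lost without either 2 h array or replicate 2 of 4 h. From 4 h to 8 h, the ribosomal protein and proteasome calls were lost without the dim replicate 1 of 8 h, and the proteasome and peroxisomal calls were lost without replicate 2 of 4 h, the latter also without replicate 2 of 8 h. Both calls from 2 h to 4 h were lost after quantile normalization and after cyclic loess, and those of the proteasome in both steps and of peroxisomal genes without scaling. Without scaling, ribosomal protein genes had medians of 0.73 and -0.35 in these steps and lost their calls, and amino acid genes had -0.33 from 4 h to 8 h and kept theirs. The medians of all genes were then 0.95 and -0.58. Each list kept its side of all genes, which this setting hardly changes. The proteasome median from 2 h to 4 h was 0.19 after quantile normalization, 0.17 after cyclic loess and 0.19 with the 75th percentile. The cytosolic ribosomal protein median from 2 h to 4 h was 0.03 and -0.42 without replicates 1 and 2 of 2 h, -0.08 without replicate 2 of 4 h, -0.02 after quantile normalization, -0.09 after cyclic loess and -0.28 with the 75th percentile. The proteasome median from 4 h to 8 h was 0.06 and -0.51 without replicates 1 and 2 of 8 h. The cytosolic ribosomal protein median from 4 h to 8 h was 0.105 without replicate 2 of 4 h, 0.01 and 0.43 without replicates 1 and 2 of 8 h, 0.11 after quantile normalization and 0.14 after cyclic loess. The amino acid median from 4 h to 8 h was 0.14 without replicate 2 of 4 h.

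Tested directly against 1 h, 8 h of drying had 55 genes higher and 130 lower. All 130 lower genes were protein-coding, and 39 of the 55 higher ones were tRNA genes. Of the 119 genes that rose at 1 h, 59 were lower at 8 h than at 1 h and 12 were still called against 0 h. Their median change against 0 h was 1.502 at 1 h, 0.85 at 2 h, 0.98 at 4 h and 0.43 at 8 h. Both counts and the fall of these medians are in part set by choosing the genes at 1 h. Chaperone genes had a median of -1.16 between 8 h and 1 h, with 0 of 30 higher and 14 lower, or 22 lower when adjusted over the list alone (camera adjusted p = 2.48e-15). SSA4 was lower by 1.25 ± 0.31, SSA3 by 1.98 ± 0.22 and HSP82 by 1.56 ± 0.33. The proteasome list had a median of -0.59, with 3 of 34 genes lower, or 1 higher and 14 lower when adjusted over the list alone (camera adjusted p = 9.41e-07). Peroxisomal genes had a median of -0.40 with 3 of 33 lower on both counts, PXA2 at -1.51 ± 0.25, and gluconeogenesis genes a median of -0.48 with 2 of 21 lower on both counts, SIP4 at -2.29 ± 0.35. Upward shifts were those of 82 cytosolic ribosomal protein genes (median 0.32), 57 amino acid biosynthesis genes (0.37) and 40 cell wall genes (0.25), each with 0 members past the threshold on either count. All 7 lists had adjusted p = 0.94 with an estimated correlation, and without scaling the medians of ribosomal protein and cell wall genes were -0.01 and -0.03, above the -0.38 of all genes. The ribosomal protein call held without scaling and that of the cell wall was lost. Without the dim replicate 1 of 8 h the calls of ribosomal protein and cell wall genes were lost, the latter also without replicate 1 of 1 h, and that of gluconeogenesis without replicate 2 of 8 h. The proteasome median was -0.27 without replicate 1 of 8 h. The peroxisomal median was -0.24 with the 75th percentile. The gluconeogenesis median was -0.26 without replicate 2 of 8 h. The cytosolic ribosomal protein median was 0.12 and 0.53 without replicates 1 and 2 of 8 h. The cell wall median was 0.12 without replicate 1 of 8 h and 0.40 with the 75th percentile.

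The count of 185 genes was 32 and 17 without replicates 1 and 2 of 1 h, 62 and 474 without replicates 1 and 2 of 8 h, and 0 without scaling. Scaling by the 75th percentile gave 78 higher and 93 lower genes, and cyclic loess 94 and 140.

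**Figure D3:**
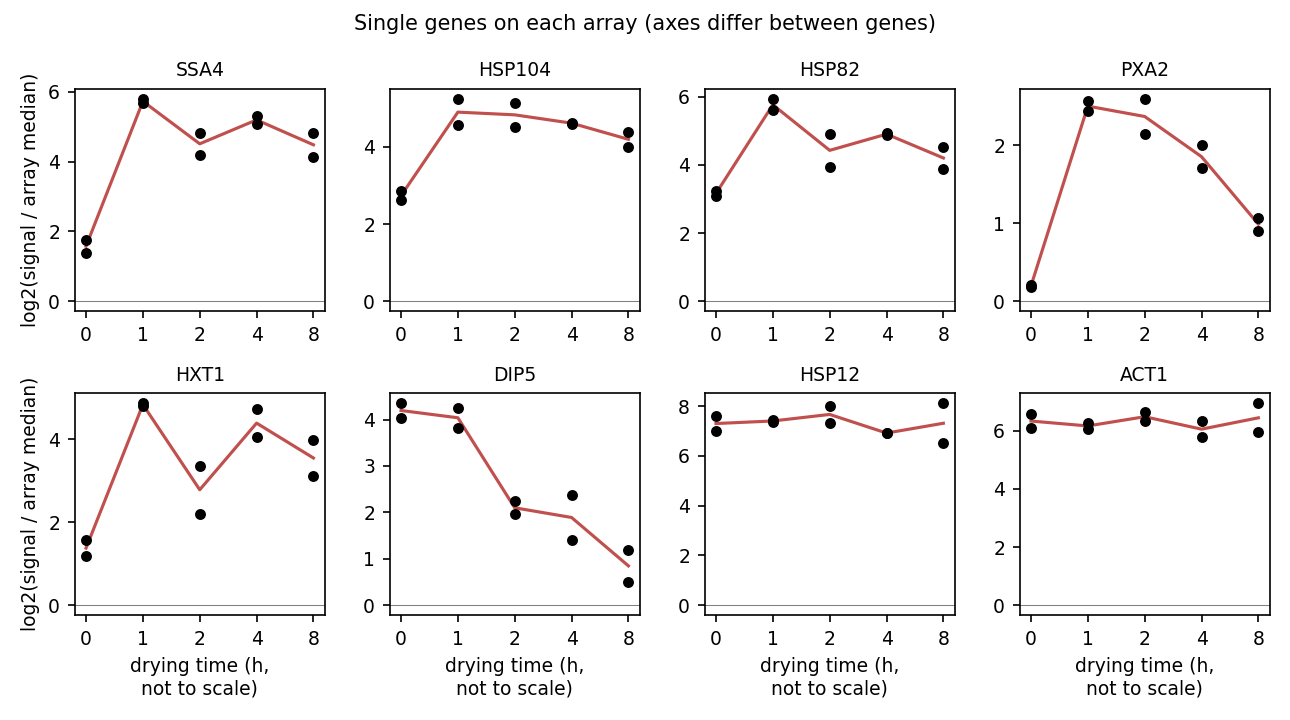
Log2 signal over the array median (vertical axis, on a scale of its own for each gene) of 8 genes at each drying time in hours (horizontal axis, not to scale), with a point for each array and a line through the means of the 2 arrays. SSA4, HSP104, HSP82, PXA2 and HXT1 are higher at 1 h than at 0 h on both arrays, DIP5 is lowest at 8 h, and the means lie between 6.92 and 7.67 for HSP12 and between 6.05 and 6.48 for ACT1, with 8 h arrays that stand apart for HSP12.

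In this poly(A)-enriched RNA, 8 tRNA genes were called lower at all 4 times and changed by -1.47 to -1.23 at 1 h and by -2.24 to -1.79 at 8 h. They were picked for those calls after the values were seen, so their fall and their contrast with the other 83 follow from the choice, and tRNA genes were no fixed list and had no set test. The other 83 had a median of -0.40 at 1 h and of 1.18, 1.14 and 1.32 at 2, 4 and 8 h, and 82 of them were higher at 2 h than at 1 h. Over all 91 tRNA genes, 9, 8, 8 and 8 were called lower and 0, 4, 13 and 10 higher at 1, 2, 4 and 8 h. The median over all tRNA genes was below 0 at 1 h and above 0 at 2, 4 and 8 h under all 5 scalings. At 8 h the 83 genes stood at 2.02 on the dim replicate 1 and 0.64 on replicate 2. Of the 91 genes, 88 were read by probe sets with a mark for a gene family or for probes otherwise not fully unique to the gene. Their values cannot be assigned to 1 gene copy.

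**Figure D4:**
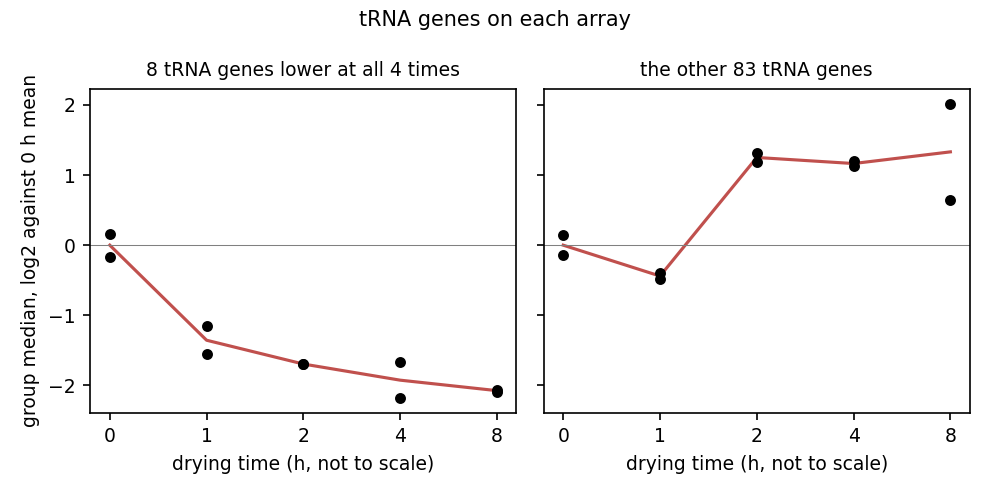
Median log2 signal of tRNA genes against their 0 h mean (vertical axis) at each drying time in hours (horizontal axis, not to scale), with a point for each array and a line through the means of the 2 arrays. The 8 genes in the left panel, picked because they were called lower at all 4 times, stand at -2.09 and -2.06 on the 8 h arrays, and the other 83 in the right panel at 2.02 and 0.64.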

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

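The tests of the dim array, of carry-over and of binding within tRNA families were chosen only after the results were seen, while the comparison with brightness-matched gene lists was planned earlier. The results here are differences between drying times, each by the test of the difference itself, and signals in probe sets outside the gene-level tests.

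The chaperone list had a median of -1.157 at 8 h against 1 h, with 14 of 30 genes lower and adjusted p = 0.94 with an estimated correlation. With the brighter 8 h array alone the median was -0.929 (camera adjusted p = 2.27e-15 at the preset correlation), which argues against the dim 8 h array as the whole cause. Of 10000 random lists matched in brightness, 0% had a median as low. With the outermost medians in each tail left out, theirs ran from -0.209 to 0.184. This argues against a brightness-dependent difference between arrays. The difference was found and tested on the same arrays. The length of drying as its cause stays an untested hypothesis, and it was not separated from time in the warm air.

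The cytosolic ribosomal protein list had a median of 0.316 at 8 h against 1 h, with 0 of 82 genes past the threshold and adjusted p = 0.94 with an estimated correlation. Without scaling its median was -0.006, above the -0.378 of all genes, and camera's adjusted p was 0.00186. Of 10000 brightness-matched lists, 0% had a median as high. With the outermost medians in each tail left out, theirs ran from -0.141 to 0.058. This argues against a brightness-dependent difference between arrays. With the brighter 8 h array alone the median was 0.123 (camera adjusted p = 0.108), so the dim array and a change with drying time cannot be told apart for these 82 genes, because 1 array is left at 8 h.

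Of 91 transfer RNA genes, which were no fixed list and had no test as a set, 41 were called higher at 2 h than at 1 h, with a median of 1.743 and 9 values below 0. The ribosomal RNA signal over the array median moved by 0.005 and the median of small nucleolar RNA genes by -0.012, which argues against more carry-over of every kind of RNA without a poly(A) tail. Against the 0 h mean, small nucleolar RNA genes stood at 0.141 and -1.059 on replicates 1 and 2 of 2 h, and at -0.288 and -0.481 at 1 h. Their value near 0 thus averages unlike arrays, and the argument rests mainly on the ribosomal RNA signal. The 3 tRNA genes with a probe set of their own had a median of 2.082 and a lowest value of 1.573, 2 of them past the threshold and TRR4 not (adjusted p = 0.0752), so binding of RNA from 1 family to shared probe sets does not account for these 3. For the other 88 genes the SD of the changes was 0.786, and binding within a family cannot be told apart from a change of each gene, because the tables do not say which tRNAs the shared probes bind. A change in tRNA levels or in their capture with drying time stays open, as untested.

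From 1 h to 2 h, 44 genes were higher and 55 lower, and the list medians were -0.847 for chaperones, -0.634 for the proteasome and 0.229 for cytosolic ribosomal proteins. From 2 h to 4 h the medians were 0.319 for the proteasome and -0.149 for cytosolic ribosomal proteins. From 4 h to 8 h, 1 gene was lower, CIN5, and the medians were -0.366 for chaperones, -0.289 for the proteasome, 0.214 for cytosolic ribosomal proteins, -0.155 for peroxisomal genes and 0.234 for amino acid biosynthesis. Between 8 h and 1 h, 55 genes were higher and 130 lower, and the other list medians were -0.587 for the proteasome, -0.481 for gluconeogenesis, -0.397 for peroxisomal genes, 0.369 for amino acid biosynthesis and 0.246 for the cell wall. Every one of these lists had adjusted p = 0.94 with an estimated correlation.

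Among the genes named at 1 h or 8 h against 0 h, the fixed genes included, 15 differed between 8 h and 1 h. Apart from the fixed genes, they had been picked for their values on the same 1 h or 8 h arrays. That choice favours a difference between these times, so the 15 are no separate support for one. Lower at 8 h on the log2 scale were DIP5 (-3.19), SIP4 (-2.29), ATG1 (-2.018), SSA3 (-1.982), GNP1 (-1.853), HSP82 (-1.564), YKL107W (-1.547), PXA2 (-1.515), SSA4 (-1.247) and FAA2 (-1.13). SGF29, at the floor on both 8 h arrays, had a fitted value of -2.692 and was at least 6.5-fold lower. Higher at 8 h were the tRNA genes SUF3 (3.375), SUF5 (3.335), HSX1 (3.203) and CDC65 (2.343). The SD over the 8 h arrays was 1.106 for SUF5, 0.985 for HSX1 and 1.192 for CDC65.

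Of 1657 probe sets without a single named gene, 10 were higher and 3 lower at 1 h than at 0 h, 7 and 9 at 2 h, 6 and 5 at 4 h, and 2 and 4 at 8 h.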

How the results depend on the processing

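Leaving out the dimmest array at 2 h and at 8 h, and testing protein-coding genes alone, were chosen after seeing the data. The other alternatives were planned. Of 2407 values of called genes under the alternatives, 1934 kept their direction and their call, 473 kept the direction and lost the call, and 0 reversed. For genes not called, 2182 of 2289 values stayed so, 31 passed and 76 changed sign. Of 969 values of called lists, 771 kept direction and call, 179 lost the call and 19 changed sign or reached 0, of which 14 were without scaling. Of 4503 values of lists not called, 103 passed, 3 of them with the other sign, and 4400 stayed uncalled. With a lone array left in a group, that array is assumed to vary like the other groups. The cause was not tested for any of the changes below, apart from the fewer genes, groups or arrays, or the unscaled shift of all genes, that a setting itself brings. Dim signals near background limit genes close to the floor.

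With each array left out in turn, the count of genes ranged from 18 to 175 at 1 h, 17 to 193 at 2 h, 26 to 130 at 4 h and 14 to 186 at 8 h against 0 h. It ranged from 59 to 374 for the F test, 0 to 215 from 1 h to 2 h, 0 to 29 from 2 h to 4 h, 0 to 38 from 4 h to 8 h and 17 to 474 between 8 h and 1 h. The number of lists ranged from 10 to 11 at 1 h, 5 to 12 at 2 h, 6 to 9 at 4 h and 2 to 7 at 8 h, and from 3 to 4, 0 to 7, 3 to 7 and 6 to 8 in the steps and between 8 h and 1 h.

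In the order 1, 2, 4 and 8 h against 0 h, then the F test, then 1 h to 2 h, the main counts were 140, 81, 78, 51, 176 and 99, with 0, 1 and 185 for 2 h to 4 h, 4 h to 8 h and 8 h against 1 h. At an adjusted p under 0.01 the counts were 53, 35, 32, 16, 77 and 3, with 0 from 4 h to 8 h and 67 for 8 h against 1 h. With eBayes without trend they were 36, 38, 27, 15, 14 and 0, with 61 for 8 h against 1 h. With the floor at 0.5 of the median they were 42, 17, 6, 6, 17 and 6, with 2, 0 and 52 for the other comparisons. With no scaling they were 1, 0, 0, 0, 1 and 0, with 0 from 4 h to 8 h and 0 for 8 h against 1 h. Without the dimmest array at 2 h and at 8 h they were 344, 252, 232, 81, 545 and 400, with 84 from 2 h to 4 h and 23 from 4 h to 8 h.

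With array weights the count was 501 at 1 h, 174 at 4 h, 406 for the F test and 0 from 4 h to 8 h. With only the 2 groups compared it was 530 at 1 h, 159 at 4 h, 0 from 4 h to 8 h and 120 for 8 h against 1 h. After cyclic loess normalization it was 144 at 2 h, 119 at 4 h, 94 at 8 h and 0 from 4 h to 8 h, and after quantile normalization 163, 141, 97 and 0. With no filter on dim probe sets it was 49 at 4 h, 27 at 8 h, 98 for the F test, 1 from 1 h to 2 h, 0 from 4 h to 8 h and 110 for 8 h against 1 h. With protein-coding genes only it was 50 at 4 h, 17 at 8 h and 25 from 1 h to 2 h. With all probe sets it was 33 from 1 h to 2 h and 2 from 4 h to 8 h, and with 75th percentile scaling 49 from 1 h to 2 h.

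The share of higher genes moved with the scaling. At 2 h, 44 higher and 37 lower genes became 96 and 48 after loess and 105 and 58 after quantile normalization. From 1 h to 2 h, 44 and 55 became 36 and 13 with the 75th percentile, 61 and 27 after loess and 65 and 48 after quantile normalization. For 8 h against 1 h, 55 and 130 became 78 and 93 with the 75th percentile and 94 and 140 after loess.

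The number of lists was 11, 10, 8 and 5 at 1, 2, 4 and 8 h, and 3, 2, 5 and 7 in the steps and for 8 h against 1 h. It was 0 in all 8 comparisons with an estimated correlation, and 0 in all 8 with fry. After loess it was 9 at 8 h, 7 from 1 h to 2 h and 0 from 2 h to 4 h, and after quantile normalization 8, 8 and 0. With no scaling it was 3 at 8 h, 5 from 1 h to 2 h, 1 from 2 h to 4 h and 3 from 4 h to 8 h, and with no filter 5 from 1 h to 2 h. Without the dimmest arrays it was 5 at 2 h and 1 from 2 h to 4 h.

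With no scaling, the median of all genes was -0.674, 0.273 and -0.291 at 2, 4 and 8 h against 0 h, -0.755, 0.953 and -0.579 in the steps and -0.378 for 8 h against 1 h. This shift turned the sign of 13 list medians and took 1 to 0, and 8 of the 14 still passed camera. All 14 stayed on their side of all genes, which was nearly fixed in advance, since this setting moves all genes of an array alike. The 14 included, at 2 h, peroxisomal genes (-0.137), general stress genes (-0.356) and chaperones (-0.006), at 4 h amino acid biosynthesis (0.116), glycolysis (0), mitochondrial ribosomal proteins (0.081) and sulfur amino acids (0.028), and at 8 h chaperones (-0.117). The others were cytosolic ribosomal proteins from 1 h to 2 h (-0.411), from 2 h to 4 h (0.729), from 4 h to 8 h (-0.346) and for 8 h against 1 h (-0.006), amino acid biosynthesis from 4 h to 8 h (-0.326) and the cell wall for 8 h against 1 h (-0.031). With each array left out in turn, the chaperone median at 8 h ranged from -0.085 without 0 h replicate 2 to 0.391. That of cytosolic ribosomal proteins from 2 h to 4 h ranged from -0.418 to 0.034 without 2 h replicate 1, and that of the proteasome from 4 h to 8 h from -0.51 to 0.064 without 8 h replicate 1. Without the dimmest arrays the latter medians were also 0.034 and 0.064.

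With the replicate block, the count was 124 at 2 h, with 80 genes higher and 44 lower, and 96 at 8 h, with 58 and 38. Deviations of arrays from their group means had correlations of -0.058 to 0.175 across genes over the 10 pairs of times, 4 of them above 0.1. The main fit was planned without a block, before the data were examined. No label says that a replicate number names 1 experiment, and the numbers were not treated as pairing the samples. The correlations were computed later and do not settle the matter. The series' design text says that duplicate experiments were done independently, so a number may stand for 1 experiment sampled at all times. Replicate 1 had the higher list median at all 5 times in 11 of 36 lists and the lower one in 0, and its actin 3'/5' ratio was higher at all 5 times, so whether a number shares something stays open.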

Other observations

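Of the 36 lists, 19 did not pass in any comparison. For trehalose metabolism, the comparison with the lowest adjusted p was 1 h against 0 h (median 0.311, adjusted p = 0.297), and for glycogen metabolism it was 2 h (-0.347, 0.101). It was 8 h against 1 h for glycerol and osmotic stress response genes (0.057, 0.377), 2 h to 4 h for 6 hydrophilins (-0.38, 0.160) and vacuolar proteases (-0.308, 0.308), and 4 h to 8 h for oxidative stress defence (0.069, 0.386) and endoplasmic reticulum chaperones (0.104, 0.362). Among energy pathways, the respiratory chain had -0.268 at 2 h (adjusted p = 0.0777) and the tricarboxylic acid cycle -0.151 (0.261). Nitrogen catabolite repressed genes had -0.346 from 1 h to 2 h (0.0898), the iron regulon -0.14 at 4 h (0.160), phosphate starvation genes -0.096 at 4 h (0.386) and multidrug resistance genes -0.325 at 8 h (0.101). Fatty acid synthesis had 0.145 from 4 h to 8 h (0.271), RNA polymerase I and III subunits 0.162 (0.498) and DNA damage response genes 0.23 (0.430) from 2 h to 4 h, cell cycle genes 0.151 from 1 h to 2 h (0.136), 5 histone genes 0.514 at 1 h (0.171) and sporulation genes -0.27 at 8 h (0.386).

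Mating and haploid-specific genes had a median signal of 0.425 of the array median, against 1.94 for all genes tested. The small nucleolar RNA genes had medians of -0.356, -0.416, -0.272 and -0.057 at 1, 2, 4 and 8 h against 0 h.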
